A study of Glycine max with 34 samples.

How the data were processed

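Gene expression was measured in soybean seeds (Glycine max, cultivar Asgrow A3237) at the early maturation stage, taken at a length of 6.0 to 7.0 mm from plants grown at 22 °C with 16 h of light and 8 h of dark. Per the labels, the seeds were fixed in ethanol and acetic acid, embedded in paraffin and cut at 8 microns, and 16 compartments were collected by laser microdissection. Of these, 6 belong to the embryonic axis, 5 to the cotyledons and 5 to the seed coat. A whole seed sample was made from ground seeds with another RNA reagent. Each of the 17 groups has 2 biological replicates on an array each, which makes 34 arrays. From each sample 2 ng of RNA was amplified, labelled with biotin and hybridized to the Affymetrix Soybean Genome Array. The labels do not say how many seeds make up a replicate or whether compartments come from the same seeds. The p-values below therefore measure the spread between these samples, and compartments may share seeds.

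The deposited values are probe set intensity on a linear scale, 1 value per probe set and array, made by the authors with GCOS 1.3. The algorithm and settings within that software are not given in the sources used here. The table holds 61170 probe sets, no detection calls and no array without a sample. On every array the mean of all probe sets, with the lowest and highest 2% set aside, was 499.9, so each array had been scaled to a common mean. Of the probe sets, 37593 are for soybean, 23350 are for Phytophthora sojae and Heterodera glycines, and 227 are controls and other sequences. The probe sets for the other organisms served as the background measured on the same arrays. For arrays, the number of arrays limits the precision.

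Signals were used as deposited, and the test values are log2 of the signal plus 16. This pseudocount makes the printed log2 differences of dim genes smaller than the ratio of their signals. A soybean probe set was tested if its signal exceeded the 95th percentile of the other-organism probe sets of that array on at least 2 arrays, which held for 28441. Where the arrays of the dimmer group above that percentile did not outnumber those below it, a fold is a lower bound, with the signals below raised to it, and is written "at least". A log2 difference beside such a bound rests in part on signals below the background. Folds are taken from means of the log2 test values, so such a bound can exceed the ratio of the mean signals printed. The bound was first used where all arrays of the group lay below, and was extended after the values had been seen. The calculations used R 4.3.3, limma 3.58.1 and data.table version 1.17.8. Plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

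The gene table used here names 9047 soybean probe sets. Of these, 8677 are tied to a single gene, 370 to several genes and the other 28546 soybean probe sets have no gene in it. Among the probe sets tested, 7448 had a single gene, and these cover 5527 genes. For 887 genes the symbol says more than a locus number, and only these are named. Each gene is read by the probe set with the highest mean signal over the 34 arrays. Probe sets with the suffixes _s_at, _x_at and _a_at may bind near-identical copies of a gene. Among the genes named below this applies to AT133, BBI-1, CHI1B1, CHR5, COPE2, CYP76O2, ELIP, F3H, FVE, GASA14, GASA33, GASA34, GER2, GST3, GSTIR, GSTU42, GY2, KTI-2, KTI-3, KTI3, LOX3, LOX9, MYB172, MYB180, PETC, PIP2-4, PIP2-6, PM3, PM30, PRP2, PRP3, RCA14, RCABETA, SBP2, SGT2, SUT1, VPE2 and VSPA. No genome positions were used.

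The 3 regions were compared with limma on the 16 compartment means, so that compartments and not arrays are the units. All other comparisons came from 1 limma fit of the 17 groups, and both fits used eBayes with an intensity trend. A probe set was called when its p, adjusted by Benjamini and Hochberg over the 28441 tested, was under 0.05 and its log2 difference was at least 1. A probe set was called enriched in a compartment when it was higher there than in the mean of the other 15 and both of its arrays lay above all 30 others. The whole seed was compared with the mean of the 16 compartments. Differences among compartments were tested with the limma F test. For the epidermis and the vascular bundle, the difference between cotyledon and axis in their contrast with parenchyma was tested as an interaction term.

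The comparisons, thresholds, most of the alternatives and 29 gene lists were chosen before the data were examined. Those lists matched product names, but the gene table holds symbols only, so 24 of them matched no gene tested. At least 5 genes were matched by 3 lists, for storage proteins, lipoxygenases and sugar transport. Another 24 lists were therefore written as symbols after the table of symbols was seen and before any comparison was computed, 17 of them on topics among the 29. They cover storage proteins, protease inhibitors, seed maturation proteins, lipoxygenases, photosynthesis, fatty acid synthesis, the phenylpropanoid and flavonoid pathway, peroxidases, cell wall proteins, sugar transport, nitrogen, gibberellin, auxin, sieve element occlusion, heat shock and vacuolar proteases. They also cover aquaporins, WRKY, MYB, bZIP and NAC factors, glutathione transferases and cytochrome P450. A list of pathogenesis-related proteins had 2 genes tested, under the minimum of 5, and was not tested. List shifts were tested with camera in limma with its preset correlation, adjusted over all 468 pairs of list and comparison. Of these pairs, 71 were called. With an estimated correlation 0 were called by camera, and 82 had an unadjusted p under 0.05 against 132 with the preset one.

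Genes were named by a rule fixed in advance. For each region comparison it takes up to 10 called genes with the largest change in each direction, and for each other comparison up to 5. Their arrays must not overlap between the groups and their mean signal in the higher group must reach 4 times the background level. These conditions were not applied to the interaction terms, where a gene needed only a call. For each compartment it takes the 3 enriched genes with the largest contrast. For each list it takes the 2 brightest members and the 2 with the largest change. The text names a selection of the genes so chosen.

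The alternatives tried were quantile normalization, scaling to a common 75th percentile, pseudocounts of 1 and 64, no filter and a filter at the 99th percentile, adjusted p alone, eBayes without a trend, the replicate number as a block, fits on the arrays compared alone, array weights, other error models for the regions, leaving out each compartment, and leaving out each array. Array weights were not run for the compartment means. For the regions, the replicate block was run on arrays with the compartment as a random block, and not on compartment means. After the arrays had been examined, the regions were also compared with the level of the hybridization controls as a covariate. The region and tissue comparisons were rerun without the 6 arrays on which those controls exceeded 2 times the median over arrays. Enriched probe sets were not run in that setting.

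The tests were checked on simulated data with known changes in 200 of 28441 probe sets. In the root against shoot meristem design, which has 2 arrays per group, 4.48% of 2-fold, 40.3% of 4-fold and 65.2% of 8-fold changes were recovered, with 8 false calls. In the cotyledon against axis design these shares were 11.9%, 55.2% and 84.8%, with 4 false calls. The F test recovered 11.9% of 4-fold and 48.5% of 8-fold changes in a single compartment, with 4 false calls. More were called in the data (62.0% by the F test), which eases the adjusted p, so these shares do not give the sensitivity here. Of 200 simulated lists of 20 genes, all but 1 of them unchanged, 5 unchanged lists had an unadjusted p under 0.05 with the preset correlation and 3 with the estimated one. Genes were simulated as independent, so the counts cannot show how either fares for genes that vary together.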

Results

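The 34 arrays gave signals for 37593 soybean probe sets in 16 microdissected compartments of the early maturation seed and in whole seeds, with 2 biological replicates per group. The embryonic axis is covered by its epidermis, parenchyma, vascular bundle, plumule, root meristem and shoot meristem. The cotyledon is covered by its vascular bundle and by the epidermis and parenchyma of its abaxial and adaxial sides. The seed coat is covered by the palisade and hourglass layers, parenchyma, hilum and aleurone. Median signals of all probe sets ran from 60.85 to 120.0 per array. The 95th percentile of probe sets for other organisms, taken as the background, had a median of 170.2 over arrays (104.3 to 263.9), and 44.2% to 59.8% of soybean probe sets exceeded it on an array. Pearson's r between the 2 replicates, across probe sets, which are not independent replicates, ran from 0.870 in the axis epidermis to 0.956 in the seed coat parenchyma. The axis vascular bundle replicates (r = 0.895) were less alike than 1 array of that group and 1 array of the root meristem (r = 0.900).

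Seed coat and embryo arrays lay apart on the first principal component. Between compartment means, the median r was 0.891 for pairs within the axis, 0.880 within the cotyledon and 0.808 within the seed coat. Between axis and cotyledon compartments it was 0.853, between axis and seed coat 0.753, and between cotyledon and seed coat 0.752. The ranges overlapped, since the aleurone was closer to the cotyledon abaxial epidermis (r = 0.795) than to the hilum (0.792), palisade (0.772) and hourglass layer (0.764). By the limma F test, 17635 of 28441 probe sets (62.0%) differed among the 16 compartments.

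**Figure D1:**
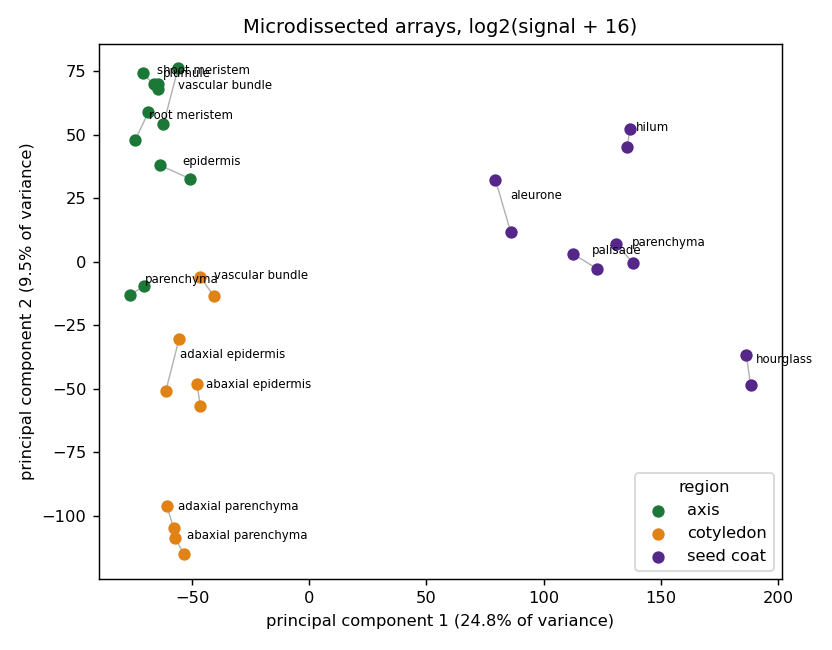
Principal components of log2 signal for the 32 microdissected arrays, as scores on component 1 (24.8% of variance) and component 2 (9.51%), with the 2 replicates of each compartment joined by a line and coloured by region. All seed coat arrays lie at 79.4 or above on component 1, and all axis and cotyledon arrays lie below 0.

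Cotyledon and axis are the storage organ and the body of the embryo. GY1, a glycinin storage protein gene, had a mean signal of 38215 over the 5 cotyledon compartments and 397.0 over the 6 axis compartments, a log2 difference of 7.45 ± 1.01 (SE; at least 77.3-fold; adjusted p = 0.00251). PIP2-8, an aquaporin gene, was higher by 5.79 ± 0.90 (at least 28.7-fold), GH by 4.42 ± 0.64 and GASA27, of the gibberellin-regulated GASA family, by 3.50 ± 0.58. Lower in the cotyledon were the seed maturation protein gene PM32 (-4.03 ± 0.84) and PARP3 (-4.31 ± 0.99). In all, 248 probe sets were higher and 178 lower in the cotyledon (220 and 215 with 75th percentile scaling). Of the 5 storage protein genes in the list fixed in advance, 2 were called higher, GY1 and GY2 (5.25 ± 0.86), and 4 were higher adjusted over the list alone (list test: adjusted p = 0.00175, and adjusted p = 0.188 with an estimated correlation). Of 16 genes of fatty acid synthesis and desaturation 2 were higher, 1 of them ACCA-1 (2.18 ± 0.45, at least 2.13-fold), and FAD2-1A, an oleate desaturase gene, stood at 2.23 ± 0.82 without passing (adjusted p = 0.0133, and adjusted p = 0.277 with an estimated correlation). ACCA-1 lost its call without axis shoot meristem replicate 2 (1.90, adjusted p = 0.0679) or axis vascular bundle replicate 1 (1.93, adjusted p = 0.0971). It also lost it with the compartment as a random block, with a replicate term (adjusted p = 0.0683) or without one (adjusted p = 0.077). The same happened without the axis plumule, cotyledon abaxial parenchyma or cotyledon adaxial parenchyma (adjusted p = 0.0556 to 0.0762). Of 29 seed maturation protein genes, PM32 and PGMPM19 (-4.11 ± 0.80) were lower and 27 were not called (adjusted p = 0.000614, and adjusted p = 0.398 with an estimated correlation). None of the 6 lipoxygenase or 7 sugar transport genes of the fixed lists was called, and 0 and 2 of them were higher adjusted over the list alone. On axis arrays the signal of the hybridization controls was 1.07 to 3.27 times the median over arrays, and on cotyledon arrays 0.565 to 1.44 times. The 6 arrays above 2 times the median include both arrays of the axis epidermis and of the plumule, so leaving them out also removes 2 of the 6 axis compartments. Without them 122 probe sets were called, 103 of them among the 426. The calls of ACCA-1 (1.36, adjusted p = 0.391), PARP3 (-4.15, adjusted p = 0.172), PM32 (-4.18, adjusted p = 0.0958) and PGMPM19 (-4.21, adjusted p = 0.0878) ended there. With the control level as a covariate 19 were called, 13 of them among the 426. For those 426 the median size of the log2 difference went from 1.80 to 1.71 and the median SE from 0.37 to 0.60. GY1 kept its call with that covariate (10.48, adjusted p = 0.0102). The calls of GY2 (7.18), GASA27 (4.88), GH (5.15), PGMPM19 (-4.91) and PIP2-8 (4.67) ended, as did those of ACCA-1 (1.90, adjusted p = 0.386), PARP3 (-2.07) and PM32 (-2.59), whose differences became smaller. With 1 compartment left out, PARP3 lost its call in 8 cases (adjusted p = 0.0517 to 0.105), PM32 in 3 (0.051 to 0.073) and PGMPM19 in 1 (0.058). PARP3 also lost its call without cotyledon adaxial epidermis replicate 1 (-4.21, adjusted p = 0.0511) or seed coat hourglass replicate 2 (-4.31, adjusted p = 0.0517), and the count fell to as few as 146 when 1 compartment, the cotyledon abaxial parenchyma, was left out.

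The seed coat was compared with the embryonic axis. AGL1L, a MADS-box gene, had a mean signal of 15507 in the seed coat and 45.4 in the axis, a log2 difference of 8.32 ± 0.44 (at least 60.7-fold; adjusted p = 1.19e-08). IFR1, an isoflavone reductase gene, was at least 67.7-fold higher (8.44 ± 0.68), and SEP1, another MADS-box gene, was higher, with the axis below the background. MYB73 (5.55 ± 0.68, at least 31.5-fold) and the glutamine synthetase gene GS1-GAMMA (5.86 ± 1.11, at least 38.9-fold) were also higher. The lipoxygenase gene LOX1.1 was lower in the seed coat (-7.82 ± 0.87, at least 93.0-fold), as were the triterpenoid hydroxylase gene CYP93E1 (-6.20 ± 0.86), the sucrose binding protein gene SBP2 (-6.04 ± 0.64, at least 30.5-fold) and the seed maturation genes PM29 (-7.28 ± 0.74, at least 40.02-fold) and PM30 (-6.57 ± 0.98). Of 29 seed maturation protein genes, 19 were lower and 1 higher (adjusted p = 3.82e-08, and adjusted p = 0.208 with an estimated correlation). Of 8 protease inhibitor genes 4 were lower, among them the Bowman-Birk gene D-II (-4.21 ± 0.87) and the Kunitz gene KTI3 (-3.95 ± 0.99; adjusted p = 0.0156, and adjusted p = 0.277 with an estimated correlation). In the fixed lists, 3 of 6 lipoxygenase genes were lower and 1 higher, 2 of 7 sugar transport genes were higher and none of 5 storage protein genes was called, with the same counts adjusted over the list alone. None of those 3 lists passed (adjusted p = 0.0915, 0.275 and 0.951). In all, 2131 probe sets were higher and 2381 lower in the seed coat (2271 and 2243 with quantile normalization). With the hybridization control level as a covariate 2176 were called, and none of the 4 protease inhibitor genes was: D-II (-4.06, adjusted p = 0.0677), KTI3 (-3.71, adjusted p = 0.134), KTI-2 (-2.88, adjusted p = 0.243) and KTI-3 (-4.56, adjusted p = 0.0713). The maturation gene PM12 (-6.71 ± 1.11) also lost its call with it (-3.83, adjusted p = 0.0827).

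The seed coat was also compared with the cotyledon. AGL1L (8.30 ± 0.46, at least 77.5-fold), IFR1 (7.74 ± 0.71, at least 79.1-fold) and MYB73 (5.80 ± 0.71, at least 43.9-fold) were higher, as was MADS28, a further MADS-box gene, with the cotyledon below the background. The nitrate transporter gene NRT1-3 (5.11 ± 0.70) and GASA9 (5.08 ± 0.46) were higher as well. GY1 (-6.69 ± 1.05), the Kunitz trypsin inhibitor gene KTI3 (-6.69 ± 1.03), FAD2-1A (-6.14 ± 0.86, at least 53.7-fold), the beta-conglycinin gene CG-1 (-6.14 ± 0.79, at least 21.6-fold) and LOX3 (-6.11 ± 0.95) were lower. Of the 5 storage protein genes in the fixed list, 4 were lower, also adjusted over the list alone (adjusted p = 0.0303, and adjusted p = 0.342 with an estimated correlation). In the list of 8 storage protein symbols 6 were lower (adjusted p = 0.00175, and adjusted p = 0.244 with an estimated correlation), among them GM2S-1, a 2S albumin gene (-7.19 ± 1.59, at least 45.1-fold). Protease inhibitors had 5 of 8 genes lower (adjusted p = 0.00484, and adjusted p = 0.216 with an estimated correlation). Seed maturation proteins had 12 of 29 lower and 1 higher (adjusted p = 0.000215, and adjusted p = 0.369 with an estimated correlation). Fatty acid synthesis had 6 of 16 lower, among them the stearoyl desaturase gene SACPD-C (-5.51 ± 0.83), and 1 higher (adjusted p = 0.00984, and adjusted p = 0.251 with an estimated correlation). Cell wall proteins and enzymes had 4 of 8 higher, the proline-rich protein gene PRP3 by 5.83 ± 0.90 (adjusted p = 0.0482, and adjusted p = 0.248 with an estimated correlation). Another of the 4, PRP1 (3.80 ± 1.18), lost its call with the hybridization control level as a covariate (3.42, adjusted p = 0.0782), with pseudocount 1 (adjusted p = 0.0584), with no filter on dim probe sets (adjusted p = 0.0518). It also lost it without any 1 of 11 compartments (adjusted p = 0.0514 to 0.103) and without any 1 of 7 arrays (adjusted p = 0.0545 to 0.105). The fixed lists of lipoxygenases (3 of 6 lower) and sugar transport (1 of 7 higher) did not pass (adjusted p = 0.192 and 0.576), and adjusted over the list alone 1 lipoxygenase gene was also higher. In all, 1517 probe sets were higher and 1675 lower in the seed coat.

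**Figure D2:**
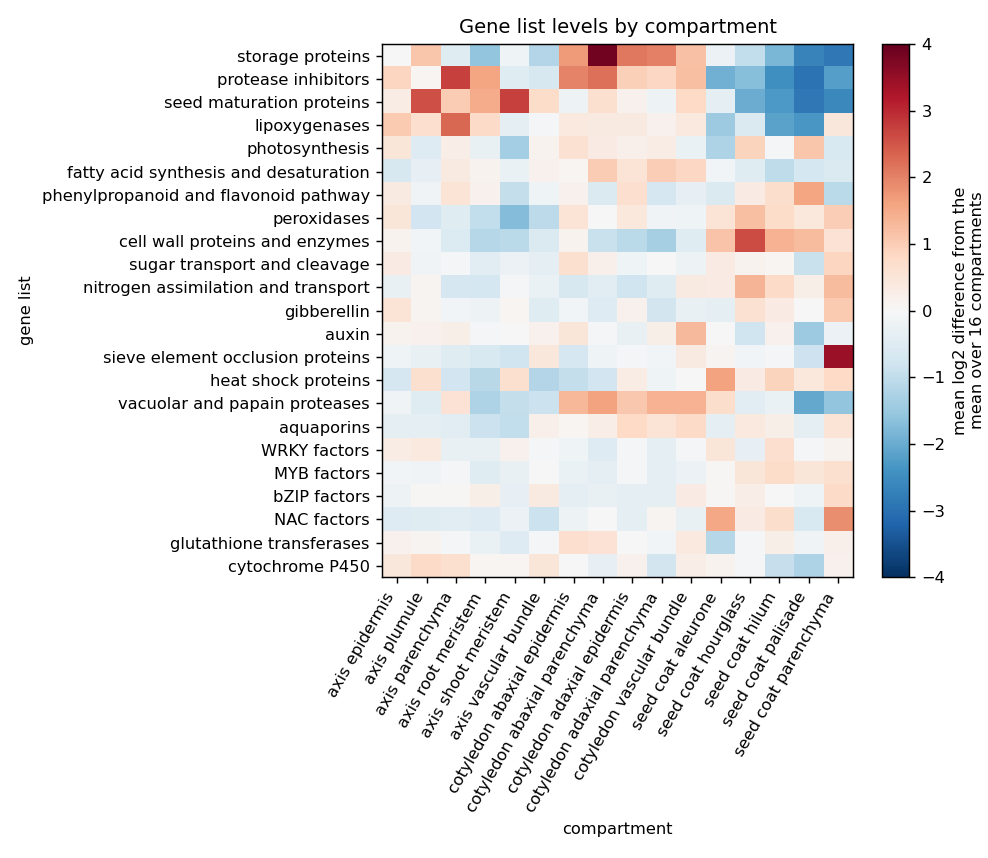
Heat map of 23 gene lists (vertical axis) in the 16 compartments (horizontal axis), coloured by the mean log2 difference of the list's genes from their mean over compartments, from blue (-4) to red (4). Storage proteins reach 3.86 in the cotyledon abaxial parenchyma and -2.85 in the seed coat parenchyma, and sieve element occlusion proteins reach 3.45 in the seed coat parenchyma.

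Within the axis, the epidermis was compared with the parenchyma beneath it. The flavonoid glucosyltransferase gene UGT78K1 was at least 85.1-fold higher in the epidermis (7.00 ± 0.57), the sucrose transporter gene SUT1 was higher by 6.16 ± 0.40, and the glutathione transferase gene GSTIR was at least 13.3-fold higher. GM2S-1 reached a mean signal of 98465 in the epidermis and 1529 in the parenchyma (6.14 ± 0.97). LRK1 was at least 31.0-fold lower in the epidermis, CHR5, a chalcone reductase gene, at least 22.6-fold lower, and P34, a papain-family seed protein gene, lower (-4.60 ± 0.82). Of 37 WRKY factor genes 4 were higher (adjusted p = 0.0133, and adjusted p = 0.181 with an estimated correlation), and of 5 peroxidase genes 2 were higher, PRX2B by 2.41 ± 0.24 (adjusted p = 0.048, and adjusted p = 0.181 with an estimated correlation). On the arrays compared alone, WRKY37 (2.56 ± 0.63, at least 5.02-fold) and WRKY47 (at least 5.21-fold) lost their calls (adjusted p = 0.0942 and 0.0865), as did the peroxidase gene Ep (adjusted p = 0.13). WRKY37 also lost its call with array weights (adjusted p = 0.108) and without axis epidermis replicate 2 (2.20, adjusted p = 0.0793) or axis parenchyma replicate 1 (1.88, adjusted p = 0.173). WRKY47 also lost its call without axis parenchyma replicate 2 (adjusted p = 0.0683). Fatty acid synthesis had 3 of 16 genes lower, FAD2-1A by -4.28 ± 0.60 (adjusted p = 0.0125, and adjusted p = 0.124 with an estimated correlation), and protease inhibitors 3 of 8 lower (adjusted p = 0.032, and adjusted p = 0.281 with an estimated correlation). Of the latter, D-II and KTI3 both lost their calls without axis epidermis replicate 1 (-3.30, adjusted p = 0.0762, and -2.55, adjusted p = 0.074), axis parenchyma replicate 1 (-3.40, adjusted p = 0.0826, and -2.28, adjusted p = 0.139) or axis parenchyma replicate 2 (-3.51, adjusted p = 0.0738, and -2.68, adjusted p = 0.075), and with array weights (adjusted p = 0.099 and 0.125). KTI3 also lost its call without axis epidermis replicate 2 (-2.41, adjusted p = 0.078), with pseudocount 1 (adjusted p = 0.051) and without a trend in the variance (adjusted p = 0.0505). In the fixed lists, 2 of 6 lipoxygenase genes were lower, 1 of 7 sugar transport genes, SWEET24 (at least 1.17-fold), was higher and none of 5 storage protein genes was called. Adjusted over the list alone, 3 lipoxygenase genes were lower and 1 higher. In all, 951 probe sets were higher and 1213 lower in the epidermis (380 and 353 on the arrays compared alone). The count was 1348 without axis parenchyma replicate 1 and 1211 without replicate 2, and both epidermis arrays had hybridization controls at 3.27 and 3.26 times the median.

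The vascular bundle of the axis held higher levels of the transcription factor genes BZIP16 (at least 33.3-fold) and MYB172 (5.55 ± 0.58, at least 26.1-fold) than the parenchyma. The vegetative storage protein gene VSPA was at least 29.5-fold higher and the aquaporin gene PIP2-4 was higher by 5.25 ± 0.76. P34 was at least 112-fold lower in the vascular bundle (-8.22 ± 0.82), and CHR5 at least 23.8-fold lower. Of 8 protease inhibitor genes, 6 were lower, D-II by -5.32 ± 0.89 (adjusted p = 4.7e-05, and adjusted p = 0.124 with an estimated correlation). Of the 6 lipoxygenase genes in the fixed list, 3 were lower, among them LOX1.1 (-4.25 ± 0.63) and LOX2 (-4.25 ± 0.74), and 5 were lower adjusted over the list alone (adjusted p = 0.00528, and adjusted p = 0.166 with an estimated correlation). GY1 (at least 2.21-fold lower) was the single storage protein gene called in the fixed list, and no sugar transport gene was called. In all, 1016 probe sets were higher and 1037 lower. The count was 1350 without axis parenchyma replicate 1, 1286 without axis parenchyma replicate 2 and 1238 without axis vascular bundle replicate 1. BBI, a Bowman-Birk inhibitor gene (at least 8.42-fold lower), lost its call without axis parenchyma replicate 1 (log2 difference -5.22, adjusted p = 0.059) or axis vascular bundle replicate 2 (-4.42, adjusted p = 0.076). KTI3 (-3.45 ± 0.68) lost its call without axis vascular bundle replicate 1 (-2.63, adjusted p = 0.0607). LOX3 (-3.11 ± 0.76), the third lipoxygenase gene, lost its call without axis parenchyma replicate 1 (-3.11, adjusted p = 0.0603), axis parenchyma replicate 2 (-3.11, adjusted p = 0.0637) or axis vascular bundle replicate 1 (-3.20, adjusted p = 0.0548). It was also not called with array weights (adjusted p = 0.0515) or without the 6 arrays with bright controls (adjusted p = 0.0757).

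In the cotyledon, the epidermis of both sides was compared with the parenchyma of both sides. UGT78K1 was at least 179-fold higher (8.02 ± 0.40) and the flavanone hydroxylase gene F3H was higher by 5.59 ± 0.61. GSTIR was at least 40.3-fold higher, the methyltransferase gene SOMT-9 higher by 6.58 ± 0.57 (at least 31.7-fold) and RCABETA, a Rubisco activase gene, higher by 5.80 ± 0.46 (at least 25.4-fold). The glycinin gene GY2 (-3.75 ± 0.40), KTI1 (-3.88 ± 0.54, at least 9.82-fold) and MYB138 (at least 12.4-fold) were lower in the epidermis. Of 34 genes of the phenylpropanoid and flavonoid pathway, 9 were higher and 3 lower (adjusted p = 0.0019, and adjusted p = 0.153 with an estimated correlation). The glucosyltransferase gene IF7GT (-3.53 ± 0.45) was among the lower ones. Gibberellin-related genes were higher in 6 of 21 and lower in 2, with GASA34 at 4.47 ± 0.26 (at least 22.0-fold) and GASA33 at least 5.15-fold higher (adjusted p = 0.0385, and adjusted p = 0.269 with an estimated correlation). Fatty acid synthesis had 3 of 16 genes lower, FAD2-1A among them (adjusted p = 0.0468, and adjusted p = 0.162 with an estimated correlation). Another of the 3, FAD3C (-1.20 ± 0.41), lost its call without any 1 of 19 arrays, for example cotyledon adaxial epidermis replicate 1 (-0.70, adjusted p = 0.289), and under 7 other settings (adjusted p = 0.0518 to 0.0764), quantile normalization and 75th percentile scaling among them. In the fixed lists, 2 of 5 storage protein genes were lower, GY2 and GY5, 1 of 6 lipoxygenase genes was lower, and of 7 sugar transport genes 1 was higher and 1 lower. Adjusted over the list alone, 2 lipoxygenase genes were also higher. In all, 1689 probe sets were higher and 1700 lower in the epidermis.

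In the cotyledon vascular bundle, the glutamine synthetase gene GS1GAMMA2 was at least 75.7-fold higher than in parenchyma (7.71 ± 0.56), and GS1-GAMMA was higher, with the parenchyma below the background. BZIP16 was at least 35.8-fold higher and GASA14 higher by 7.17 ± 0.39 (at least 70.5-fold), and MYB145 was higher, with the parenchyma below the background. KTI1 (-5.03 ± 0.67, at least 26.6-fold), the aldehyde dehydrogenase gene ALDH2B4 (-4.61 ± 0.67) and GY5 (-4.18 ± 0.62) were lower. Of the 5 storage protein genes in the fixed list 2 were lower, and 4 were lower adjusted over the list alone (adjusted p = 0.0361, and adjusted p = 0.244 with an estimated correlation). Of 6 lipoxygenase genes 2 were higher and 2 lower, LOX7 at 3.24 ± 0.66 and LOX2 at -3.49 ± 0.64, and of 7 sugar transport genes SWEET13 was at least 3.67-fold lower, with the same counts adjusted over the list alone. In all, 1890 probe sets were higher and 1145 lower. The count was 1982 without cotyledon vascular bundle replicate 1 and 1908 without replicate 2, and the call of BBI (-5.03 ± 1.11) was lost without replicate 2 (-4.08, adjusted p = 0.0923).

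Cotyledon and axis shared part of these tissue differences. Among 28441 probe sets, 475 were higher in the epidermis than in the parenchyma of both organs where 56.5 are expected if the calls were independent, 390 were lower in both (72.5 expected) and 76 went opposite ways (128.9 expected). For the vascular bundle, 546 were higher in both (67.5 expected), 325 lower in both (41.7) and 100 opposite (109.8). UGT78K1 and GSTIR were higher in the epidermis of both organs, and BZIP16 in the vascular bundle of both. The difference between the organs, tested as an interaction, passed for 952 probe sets in the epidermis and 864 in the vascular bundle. GDH1, a glutamate dehydrogenase gene, was higher in the axis epidermis (at least 11.4-fold) and lower in the cotyledon epidermis (at least 5.89-fold), a log2 difference of -8.85 ± 0.55 (-6.07 with signals below the background raised to it, as for both axis parenchyma arrays). SGT2, a soyasaponin glycosyltransferase gene, went the other way, with 4.92 in the cotyledon and -2.92 in the axis (7.84 ± 0.77). In the vascular bundle, the Kunitz inhibitor genes KTI-2 and KTI-3 were higher than in parenchyma in the cotyledon (4.51 and 4.39) and lower in the axis (-3.28 and -2.98). Protease inhibitors passed as a list for both tissues, with 3 of 8 genes higher in each. For the epidermis the adjusted p = 0.0179, and adjusted p = 0.248 with an estimated correlation, and for the vascular bundle adjusted p = 0.00135, and adjusted p = 0.158 with an estimated correlation. The phenylpropanoid and flavonoid pathway passed with 8 of 34 higher for the epidermis, and with 6 higher and 1 lower for the vascular bundle. Adjusted p was 0.000187 and 0.00836 (0.124 and 0.181 with an estimated correlation). Seed maturation proteins had 4 of 29 higher for the vascular bundle (adjusted p = 0.035, and adjusted p = 0.358 with an estimated correlation). The fixed storage protein list was lower for the epidermis, with 2 of 5 genes called and 2 adjusted over the list alone (adjusted p = 0.0402, and adjusted p = 0.246 with an estimated correlation). The fixed lipoxygenase list was higher for the vascular bundle, with 2 of 6 called and 3 adjusted over the list alone (adjusted p = 0.0133, and adjusted p = 0.187 with an estimated correlation). Of these, LOX10 stood at 5.08 ± 1.18 (3.61 with signals raised to the background). It lost its call without axis parenchyma replicate 2 (4.95), axis vascular bundle replicate 2 (3.81) or cotyledon vascular bundle replicate 2 (4.77). The auxin list passed for the vascular bundle with 1 of 9 genes called, the transporter gene PIN2A (adjusted p = 0.0402, and adjusted p = 0.162 with an estimated correlation). PIN2A lost its call without axis parenchyma replicate 1 (3.70). Of these groups, PIN2A and the protease inhibitor gene BBI-2 exceeded the background in axis parenchyma alone. Neither was shown to be higher in a vascular bundle. The counts for both tissues fell without axis parenchyma replicate 2, and that of the vascular bundle without other arrays too.

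The abaxial side of the cotyledon, which faces the seed coat, was compared with the adaxial side, where the 2 cotyledons meet. In the epidermis SUT1 was higher on the abaxial side (5.70 ± 0.40), as were the sugar exporter gene SWEET24 (at least 4.93-fold) and SCB1, a seed coat BURP-domain protein gene (at least 20.5-fold). The mean signal of SWEET24 was highest in the seed coat aleurone (69414) and that of SCB1 in the hourglass layer (93968). Whether seed coat tissue was carried over into the abaxial epidermis was not tested. 4CL3, a coumarate ligase gene, was at least 32.8-fold lower on the abaxial side, MYB11 lower (-4.49 ± 0.54, at least 17.3-fold) and PIP2-8 lower (-4.46 ± 0.75). Of 18 aquaporin genes 5 were lower, PIP2-6 by -2.26 ± 0.32 (adjusted p = 0.00119, and adjusted p = 0.124 with an estimated correlation), and of 16 fatty acid synthesis genes 3 were lower (adjusted p = 0.0431, and adjusted p = 0.16 with an estimated correlation), FAD2-2 by -1.36 ± 0.20. Without abaxial epidermis replicate 2 the other 2, FAD2-1A (-2.80, adjusted p = 0.0513) and SACPD-C (-1.14, adjusted p = 0.194), lost their calls. SACPD-C also lost its call without adaxial epidermis replicate 2 (-1.31, adjusted p = 0.109). The aquaporin gene PIP2-4 (-3.32 ± 0.76) lost its call without abaxial epidermis replicate 1 (-3.11, adjusted p = 0.111), abaxial epidermis replicate 2 (-3.54, adjusted p = 0.0531) or adaxial epidermis replicate 2 (-3.09, adjusted p = 0.101). In the fixed lists, 1 of 5 storage protein genes, GY2 (-3.29 ± 0.57), was lower (2 adjusted over the list alone), and 1 of 6 lipoxygenase genes, LOX9 (1.78 ± 0.42, at least 2.86-fold), and 1 of 7 sugar transport genes, SWEET24, were higher. In all, 536 probe sets were higher and 466 lower (476 and 505 with 75th percentile scaling, 271 and 301 on the arrays compared alone). The count was 560 without abaxial epidermis replicate 1, 536 without replicate 2 and 595 without adaxial epidermis replicate 2. PRP3 (4.55 ± 0.84, at least 17.9-fold) lost its call without abaxial epidermis replicate 1 (3.37, adjusted p = 0.0772).

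Between the abaxial and adaxial parenchyma of the cotyledon fewer probe sets differed, 172 higher and 118 lower. GY5 (4.54 ± 0.71), GASA22 (4.73 ± 0.49) and the cytochrome P450 gene CYP72A67 (4.01 ± 0.46) were higher on the abaxial side, and CCR was at least 10.6-fold lower. Of 29 seed maturation protein genes 7 were higher, PM1 by 3.54 ± 0.46, and 1 lower (adjusted p = 4.57e-05, and adjusted p = 0.147 with an estimated correlation). Storage proteins had 2 of 8 genes higher (adjusted p = 0.00217, and adjusted p = 0.153 with an estimated correlation), protease inhibitors 3 of 8 (adjusted p = 0.00477, and adjusted p = 0.181 with an estimated correlation), and glutathione transferases 1 of 21, GSTU37 by 3.37 ± 0.47 (adjusted p = 0.00272, and adjusted p = 0.124 with an estimated correlation). Of the lists fixed in advance, 1 of 5 storage protein genes was higher and 1 of 6 lipoxygenase genes lower, with 1 lipoxygenase gene also higher adjusted over the list alone, and no sugar transport gene was called. The count of 290 was 144 and 178 without abaxial parenchyma replicate 1 or 2, and 190 and 162 without adaxial parenchyma replicate 1 or 2. PM13 (-4.82 ± 0.86, at least 15.3-fold) lost its call without abaxial parenchyma replicate 2 (-3.80, adjusted p = 0.109), and KTI1 (3.89 ± 0.77) without adaxial parenchyma replicate 2 (3.56, adjusted p = 0.128) or either abaxial array (3.91, adjusted p = 0.0741, and 3.86, adjusted p = 0.0763). KTI-2 (2.99 ± 0.48, at least 7.56-fold) lost its call without abaxial parenchyma replicate 1 (2.40, adjusted p = 0.0561) and on the arrays compared alone (adjusted p = 0.0561). KTI1 also lost its call with pseudocount 1 (adjusted p = 0.0887). The storage protein gene BG7S-1 (at least 6.11-fold) lost its call without adaxial parenchyma replicate 2 (adjusted p = 0.0549).

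The root meristem of the axis was compared with the shoot meristem. The Bowman-Birk genes BBI-1 and BBI-2 were at least 26.5-fold and 15.4-fold higher in the root meristem, and HIDH, an isoflavone biosynthesis gene, was higher by 6.41 ± 0.96 (at least 28.9-fold). The small heat shock protein gene HSP23.9 was at least 94.0-fold lower in the root meristem, the maturation protein gene SLE2 at least 62.9-fold lower, and PM1 (-5.87 ± 0.46) and GM2S-1 (-6.91 ± 0.97) were lower. Of 29 seed maturation protein genes 9 were lower and 1 higher in the root meristem (adjusted p = 0.000525, and adjusted p = 0.167 with an estimated correlation). Protease inhibitors had 4 of 8 higher and 1 lower (adjusted p = 0.0167, and adjusted p = 0.244 with an estimated correlation). Of these, D-II (3.42 ± 0.89) lost its call without root meristem replicate 1 (3.20, adjusted p = 0.114), root meristem replicate 2 (3.65, adjusted p = 0.0551) or shoot meristem replicate 1 (2.86, adjusted p = 0.151). The phenylpropanoid and flavonoid pathway had 10 of 34 higher and 1 lower, CHI1B1 at 5.15 ± 0.48 (adjusted p = 0.00572, and adjusted p = 0.17 with an estimated correlation), and photosynthesis 4 of 9 higher and 1 lower (adjusted p = 0.0278, and adjusted p = 0.306 with an estimated correlation). The higher photosynthesis genes include ELIP, a light-induced protein gene (4.07 ± 0.43, at least 15.9-fold), and the lower one is RCABETA (at least 1.74-fold). By the fixed lists, 2 of 6 lipoxygenase genes were higher, LOX10 (at least 7.22-fold) and LOX7 (at least 7.31-fold), and LOX1.1 (-2.13 ± 0.63) was lower, with 3 higher adjusted over the list alone. No storage protein or sugar transport gene was called. In all, 1246 probe sets were higher and 875 lower in the root meristem, and the count was 1205 without root meristem replicate 1.

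The plumule, the first leaves of the embryo, was compared with the shoot meristem. GY1 was at least 5.65-fold higher in the plumule (4.85 ± 0.94), SALI5-4A at least 7.27-fold and F3H at least 13.0-fold. COI1, a jasmonate receptor gene, was lower in the plumule (-3.71 ± 0.42), as was H1 (-4.40 ± 0.52). Photosynthesis had 4 of 9 genes higher, RCAALPHA by 2.29 ± 0.26 (adjusted p = 0.048, and adjusted p = 0.358 with an estimated correlation), and the list's median went from 0.47 to 0.15 with quantile normalization. RCABETA (3.02 ± 0.65) lost its call without plumule replicate 2 (2.89, adjusted p = 0.0536) or shoot meristem replicate 1 (2.56, adjusted p = 0.0818). Peroxidases had 2 of 5 higher, PRX2B by 1.65 ± 0.24 and PRX3, which lost its call without plumule replicate 2 (1.68, adjusted p = 0.0586) or shoot meristem replicate 2 (1.65, adjusted p = 0.0567; list test: adjusted p = 0.0201, and adjusted p = 0.153 with an estimated correlation), and the phenylpropanoid and flavonoid pathway 4 of 34 (adjusted p = 0.0468, and adjusted p = 0.281 with an estimated correlation). Among the genes fixed in advance, 2 of 5 storage protein genes were higher, GY1 and GY5 (3.45 ± 0.71), and 3 adjusted over the list alone, while none of 6 lipoxygenase genes was called, 3 being higher adjusted over the list alone, and none of 7 sugar transport genes. In all, 979 probe sets were higher and 501 lower in the plumule. Quantile normalization shifted the median of all probe sets by -0.11, and the hybridization controls of both plumule arrays were above 2 times the median. The count was 789 and 803 without plumule replicate 1 or 2 and 881 without shoot meristem replicate 1, and without the latter HIDH (4.85 ± 0.96, at least 9.73-fold) lost its call (3.14, adjusted p = 0.109).

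Each seed coat layer was compared with the seed coat parenchyma. In the aleurone, the seed maturation gene PM12 reached a mean signal of 48117 against 360.45 in the parenchyma. Its log2 difference was 7.97 ± 1.04 (at least 155-fold from the means of log values, which exceeds the ratio of those mean signals). PM30 reached 16444 against 136.35 (7.44 ± 0.59, at least 85.4-fold). MFT was at least 86.8-fold higher and UGT78K1 at least 60.5-fold. GASA6 was at least 125-fold lower in the aleurone, and the sugar exporter gene SWEET17 (-7.31 ± 0.56, at least 136-fold) and the lipoxygenase genes LOX7 (-7.32 ± 0.76, at least 157-fold) and LOX9 (-7.22 ± 0.42) were lower. Of 29 seed maturation protein genes 14 were higher and 2 lower (adjusted p = 4.12e-06, and adjusted p = 0.124 with an estimated correlation). Storage proteins had 5 of 8 higher (adjusted p = 0.0125, and adjusted p = 0.182 with an estimated correlation), GM2S-1 at least 12.2-fold, and vacuolar and papain proteases 4 of 5, VPE by 3.22 ± 0.32 (adjusted p = 0.0167, and adjusted p = 0.153 with an estimated correlation). Sieve element occlusion proteins had 4 of 7 lower, SEOF at least 41.3-fold (adjusted p = 0.0278, and adjusted p = 0.182 with an estimated correlation), and glutathione transferases 10 of 21 lower and 1 higher, GST3 by -5.78 ± 0.70 (at least 46.8-fold; adjusted p = 0.0133, and adjusted p = 0.153 with an estimated correlation). Of the lists fixed in advance, 3 of 5 storage protein genes were higher, 1 of 6 lipoxygenase genes was higher and 2 lower, and 2 of 7 sugar transport genes were lower, with the same counts adjusted over the list alone. In all, 2386 probe sets were higher and 2806 lower in the aleurone. The count was 3424 without seed coat parenchyma replicate 2. GY1 (3.62 ± 0.94, at least 5.05-fold) lost its call without that array (2.22, adjusted p = 0.201) or without aleurone replicate 1 (2.43, adjusted p = 0.158), whose hybridization controls were at 2.33 times the median. The protease gene P34 (2.64 ± 0.82, at least 5.06-fold) lost its call without the same arrays (1.25, adjusted p = 0.448, and 1.86, adjusted p = 0.246), and on the arrays compared alone (adjusted p = 0.0743). GY7 (at least 4.30-fold higher) lost its call without aleurone replicate 2 (adjusted p = 0.0566).

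The hourglass layer, a single layer of thick-walled cells under the palisade, was higher than the parenchyma for MYB172 (5.79 ± 0.58), PM3 (6.54 ± 0.52, at least 90.5-fold), the cell wall gene PRP2 (at least 23.3-fold) and the proanthocyanidin gene LAR1 (at least 12.7-fold). SWEET17 (-6.62 ± 0.56, at least 95.7-fold), the linoleate desaturase gene FAD3C (-6.55 ± 0.58, at least 41.9-fold) and MYB138 (-6.32 ± 0.70, at least 74.9-fold) were lower. The phenylpropanoid and flavonoid pathway had 14 of 34 genes higher and 2 lower, F3H by 5.71 ± 0.86 (adjusted p = 0.00119, and adjusted p = 0.147 with an estimated correlation). Photosynthesis had 5 of 9 higher, RCA14 by 2.77 ± 0.28 (adjusted p = 0.00347, and adjusted p = 0.188 with an estimated correlation), and sieve element occlusion proteins 5 of 7 lower, SEOE at least 8.56-fold (adjusted p = 0.0133, and adjusted p = 0.162 with an estimated correlation). The photosynthesis gene CHLH (at least 3.52-fold) lost its call without any 1 of the 4 arrays compared (adjusted p = 0.0786 to 0.13) and with pseudocount 1 (adjusted p = 0.101). By the fixed lists, 3 of 5 storage protein genes were higher, GY1 by 4.80 ± 0.94 (at least 11.5-fold), 1 of 6 lipoxygenase genes was higher and 1 lower (2 higher adjusted over the list alone), and 2 of 7 sugar transport genes were higher, SWEET13 by 3.28 ± 0.57, and 1 lower (2 lower adjusted over the list alone). In all, 2197 probe sets were higher and 3279 lower, so that 40.1% of the calls were higher. With 75th percentile scaling, which shifts the median of all probe sets by 0.19, 2702 were higher and 2555 lower, or 51.4%.

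In the hilum, the scar where the seed joins the pod, GSTU42, a glutathione transferase gene, reached a mean signal of 35525 against 120.8 in the parenchyma (8.05 ± 0.63, at least 225-fold). The germin-like protein gene GER2 was at least 64.5-fold higher, MYB172 higher by 6.68 ± 0.58 and the anthocyanidin synthase gene ANS2 by 6.45 ± 0.67. LOX7 was at least 172-fold lower, BZIP16 at least 72.9-fold lower and SOMT-9 at least 45.8-fold lower. The phenylpropanoid and flavonoid pathway had 16 of 34 higher and 1 lower (adjusted p = 4.7e-05, and adjusted p = 0.124 with an estimated correlation), sieve element occlusion proteins 5 of 7 lower (adjusted p = 0.0096, and adjusted p = 0.154 with an estimated correlation) and lipoxygenases 4 of 9 lower (adjusted p = 0.0134, and adjusted p = 0.182 with an estimated correlation). Among the genes fixed in advance, no storage protein gene was called, 2 of 6 lipoxygenase genes were lower (with 1 higher adjusted over the list alone) and 2 of 7 sugar transport genes were lower, SWEET24 by -5.93 ± 0.71. In all, 1975 probe sets were higher and 2305 lower in the hilum (2225 and 2112 with 75th percentile scaling), and the count was 2788 without seed coat parenchyma replicate 2.

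In the palisade layer, ANR1, an anthocyanidin reductase gene, was at least 315-fold higher than in the parenchyma (8.50 ± 0.68), LAR1 at least 66.7-fold, the coumarate ligase gene 4CL4 at least 124-fold, and ANS2 was higher by 8.21 ± 0.67. MYB138 was at least 96.4-fold lower, BZIP16 at least 96.0-fold and the soyasaponin gene SGT2 at least 62.6-fold. Of 34 phenylpropanoid and flavonoid genes, 18 were higher and 3 lower (adjusted p = 4.12e-06, and adjusted p = 0.0961 with an estimated correlation). Photosynthesis had 5 of 9 genes higher, PETC at least 6.14-fold (adjusted p = 0.00187, and adjusted p = 0.181 with an estimated correlation). Lower as lists were sieve element occlusion proteins (6 of 7, SEOA at least 31.5-fold; adjusted p = 0.00175, and adjusted p = 0.124 with an estimated correlation), NAC factors (8 of 13, NAC12 at least 5.52-fold; adjusted p = 0.00941, and adjusted p = 0.244 with an estimated correlation) and lipoxygenases (4 of 9, LOX9 by -7.60 ± 0.42; adjusted p = 0.0176, and adjusted p = 0.188 with an estimated correlation). NAC27 (-4.66, at least 9.26-fold, adjusted p = 0.0114) lost its call without palisade replicate 1 (-2.26, adjusted p = 0.43) or parenchyma replicate 2 (-3.80, adjusted p = 0.151), and on the arrays compared alone (adjusted p = 0.0567). The same arrays ended the call of the photosynthesis gene CAB3 (1.21 ± 0.31), which stood at 1.07 (adjusted p = 0.0856) and 1.06 (adjusted p = 0.0844) without them. Of the lists fixed in advance, no storage protein gene was called, 2 of 6 lipoxygenase genes were lower, and of 7 sugar transport genes 3 were lower, SWEET24 (-7.80 ± 0.71, at least 220-fold) and SWEET17 (-7.07 ± 0.56) among them, and 1 higher, with the same counts adjusted over the list alone. In all, 2058 probe sets were higher and 2547 lower in the palisade.

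Probe sets enriched in 1 compartment against all others numbered 7398: 1463 for the 6 axis compartments, 1336 for the 5 cotyledon compartments and 4599 for the 5 seed coat compartments. Were arrays unrelated, both of a compartment would lie above the other 30 for 57.3 probe sets, or 917.5 over all 16. This precedes the test and fold minimum and, as replicates are related, is no fair measure of chance. In the seed coat, SWEET17 was enriched in the parenchyma (mean signal 30616 ± 3380, SD, n = 2, against 366.9 in the next compartment), GASA6 also in the parenchyma (22800 ± 2455 against 322.8), GSTU42 in the hilum (35525 ± 2113 against 168.9) and DFR1, a dihydroflavonol reductase gene, in the palisade (42254 ± 2955 against 4777). WRKY51 marked the aleurone (22658 ± 5903 against 3583) and MYB48 the hourglass layer (28732 ± 9443 against 10758). In the cotyledon, KTI1 marked the abaxial parenchyma (14968 ± 366 against 1024), where GY5 was enriched too (33060 ± 4115 against 3798). CYP76O2 marked the vascular bundle (26166 ± 1353 against 1586), FLS1, a flavonol synthase gene, the adaxial epidermis (9129 ± 703 against 1794), ALDH2B4 the adaxial parenchyma (18049 ± 864 against 6213) and SUT1 the abaxial epidermis (35616 ± 7318 against 21776). In the axis, BBI-1 marked the root meristem (5486 ± 1292 against 189.7), PM22 the shoot meristem (6242 ± 1259 against 1731), CHR5 the parenchyma (5670 ± 627 against 1635), VSPA the vascular bundle (6805 ± 3955 against 1391) and PGMPM18 the plumule (18222 ± 1431 against 9994). GM2S-1 was enriched in the axis epidermis (98465 ± 6838 against 71456 in the cotyledon adaxial epidermis), and its call ended with quantile normalization. By compartment, the axis vascular bundle had 129 enriched probe sets, the axis epidermis 263 and the cotyledon adaxial epidermis 165. The count rose without replicate 2 of the first and without either replicate of the other compartments. A lone array then has to lie above the others, which loosens the rule, so a rise is in part built in.

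**Figure D3:**
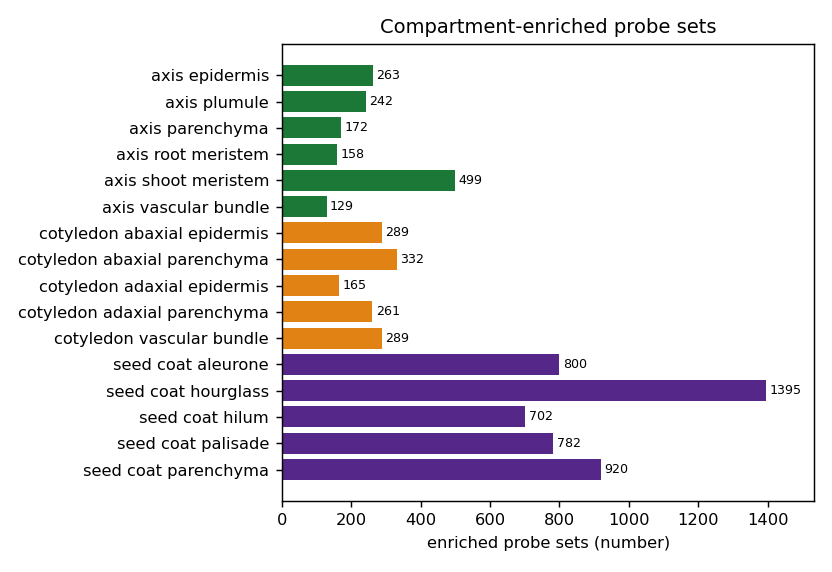
Bars give the number of enriched probe sets (horizontal axis) in each of the 16 compartments (vertical axis), coloured by region. The hourglass layer has the most, 1395, and the axis vascular bundle the fewest, 129.

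**Figure D4:**
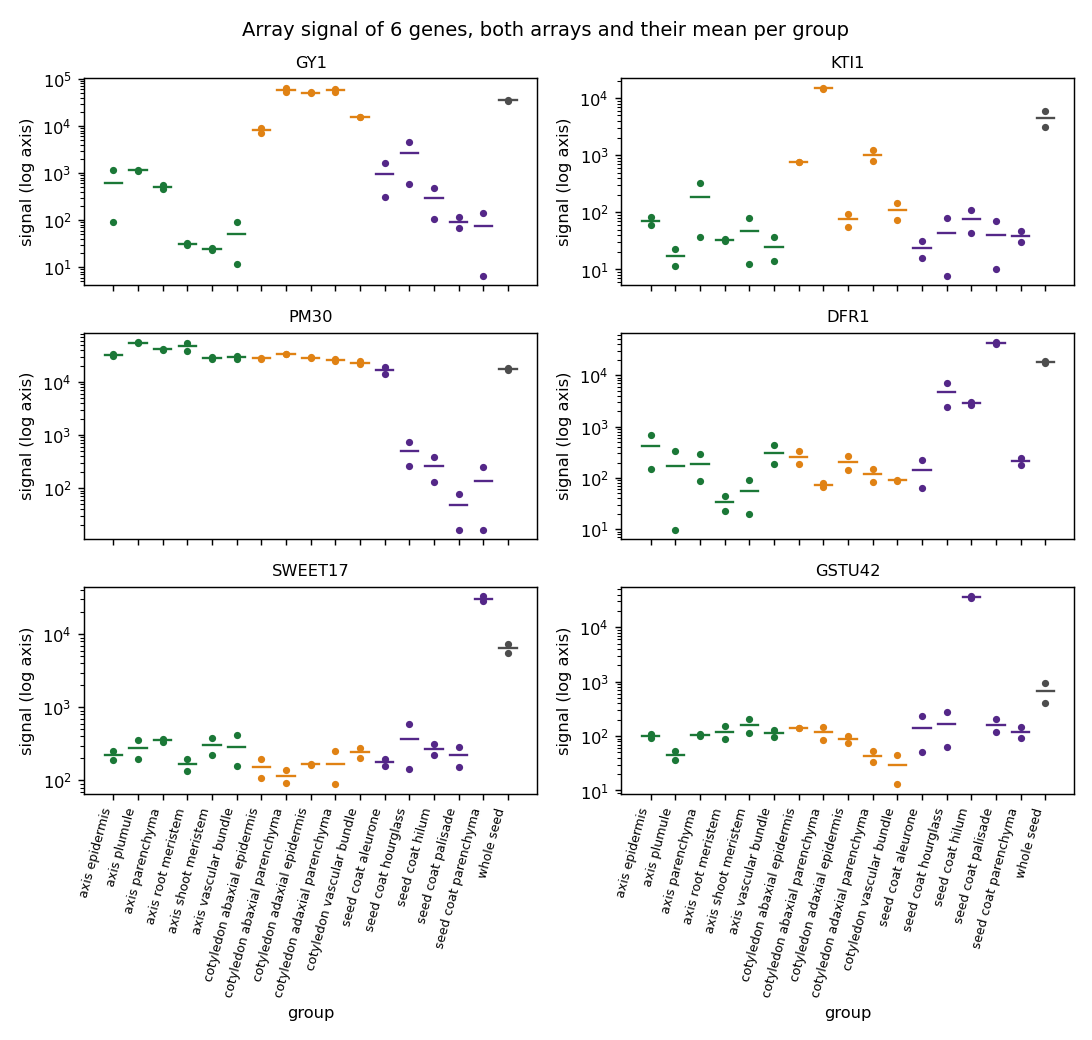
Array signal on a log axis for 6 genes in the 17 groups, with a point per array and a line at the mean of the 2 arrays, picked for the plot after their values were seen. GY1 is highest in the cotyledon abaxial parenchyma (59161), KTI1 there as well (14968), DFR1 in the palisade (42254), SWEET17 in the seed coat parenchyma (30616) and GSTU42 in the hilum (35525), while PM30 ranges from 54493 in the plumule to 47.9 in the palisade.

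The whole seed, which pools all tissues, was compared with the mean of the 16 compartments on the log scale. GH (4.63 ± 0.49), SOYAP2 (2.03 ± 0.27) and PETC, a photosynthetic electron transport gene (2.00 ± 0.33), were higher in the whole seed. MYB180 (-1.28 ± 0.19), COPE2 (-1.20 ± 0.22) and FVE (-1.15 ± 0.15) were lower. Of 34 phenylpropanoid and flavonoid genes, 21 were higher, DFR1 by 5.90 ± 0.62 (at least 41.7-fold; adjusted p = 3.55e-06, and adjusted p = 0.0961 with an estimated correlation). All 8 protease inhibitor genes were higher, KTI1 by 5.17 ± 0.56 (at least 14.03-fold; adjusted p = 0.00175, and adjusted p = 0.16 with an estimated correlation), and of these D-II (2.52 ± 0.65) lost its call without whole seed replicate 1 (2.59, adjusted p = 0.0571) or replicate 2 (2.45, adjusted p = 0.1). Also higher were 13 of 21 gibberellin-related genes (adjusted p = 0.000718, and adjusted p = 0.14 with an estimated correlation), 8 of 15 nitrogen genes (adjusted p = 0.0267, and adjusted p = 0.181 with an estimated correlation) and 4 of 5 vacuolar and papain protease genes (adjusted p = 0.026, and adjusted p = 0.154 with an estimated correlation). Of these, GASA14 (1.22 ± 0.33) lost its call without whole seed replicate 1 (1.32, adjusted p = 0.0582) or replicate 2 (1.13, adjusted p = 0.148). CYSP1 (2.62 ± 0.68, at least 1.56-fold) lost its call without replicate 2 (2.29, adjusted p = 0.152). Of the fixed lists, storage proteins had 3 of 5 higher and 4 adjusted over the list alone, GY1 by 5.13 ± 0.68 (adjusted p = 0.0153, and adjusted p = 0.182 with an estimated correlation). Lipoxygenases had 4 of 6 higher and 5 adjusted over the list alone, LOX9 by 5.94 ± 0.31 (adjusted p = 0.0133, and adjusted p = 0.187 with an estimated correlation), and sugar transport 3 of 7, SWEET17 by 4.37 ± 0.41 (adjusted p = 0.152). In all, 3400 probe sets were higher and 2098 lower, so that 61.8% of the calls were higher. With 75th percentile scaling, which shifts the median of all probe sets by -0.13, 2849 were higher and 2740 lower, or 51.0%. A mean of log values lies below the log of a mixture, and the count was 2340 without whole seed replicate 2, where FVE no longer reached the fold minimum (-0.84, adjusted p = 0.00583).

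Lists written as symbols on the topics of the fixed lists also passed. Storage proteins had 2 of 8 genes higher in the cotyledon against the axis (adjusted p = 0.00226, and adjusted p = 0.248 with an estimated correlation), 3 of 8 lower in the cotyledon vascular bundle (adjusted p = 0.0303, and adjusted p = 0.244 with an estimated correlation) and 5 of 8 higher in the whole seed (adjusted p = 0.0124, and adjusted p = 0.182 with an estimated correlation). Lipoxygenases had 4 of 9 lower in the axis vascular bundle (adjusted p = 0.00119, and adjusted p = 0.14 with an estimated correlation) and 6 of 9 higher in the whole seed (adjusted p = 0.00836, and adjusted p = 0.17 with an estimated correlation). For the vascular bundle interaction 3 of 9 lipoxygenases were higher (adjusted p = 0.00134, and adjusted p = 0.142 with an estimated correlation). Other lists passed in no comparison. The lowest adjusted p was 0.0512 for 47 bZIP factor genes, 0.0639 for 50 MYB factor genes, 0.0914 for 18 cytochrome P450 genes, 0.104 for 5 heat shock protein genes and 0.154 for the 11 sugar transport symbols.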

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

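Among the tests in this part, those of the hybridization control level, of cells carried over into the aleurone and of the preparation of the whole seed were chosen after the result was seen. The division of the carried-over cells into cotyledon and axis sources, and the bound on the interval, were set after a first run over all sources, and the count of splits that keep replicates together was added after the splits had been seen. Signals were compared with the background in the interactions after their values had been seen.

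The contrast of epidermis with parenchyma differed between cotyledon and axis for 952 probe sets, and the contrast of vascular bundle with parenchyma for 864, by the interaction test. For the epidermis, the difference (cotyledon minus axis, log2) was 7.84 for SGT2, 7.37 for SOMT-9, 6.83 for CHR5, 6.63 for AT133 and 6.07 for GT4, and -8.85 for GDH1, -5.32 for GY2, -4.77 for VPE2, -4.74 for GY5 and -3.59 for NIR. SGT2 and GDH1 were called in opposite directions in the 2 organs. CHR5 was called in the axis alone, where it was at least 22.6-fold lower, and 7 of its 8 cotyledon arrays lay below the background. SOMT-9, AT133, GT4, GY2, VPE2 and GY5 were called in the cotyledon alone, and NIR in neither. With signals below the background raised to it, the difference was 5.77 for SOMT-9, 4.69 for CHR5, 3.97 for AT133, 4.66 for GT4, -6.07 for GDH1, -3.26 for VPE2 and -3.25 for GY5. All 12 arrays lay below it for NIR (-0.13), so its difference rests on no signal above the background. NIR lost its call without any 1 of 9 arrays, for example axis parenchyma replicate 1 (-3.32, adjusted p = 0.129).

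For the vascular bundle, the difference was 8.58 for CHR5, 7.80 for KTI-2, 7.37 for KTI-3, 7.25 for AT133 and 7.13 for AMS1, and -4.79 for GY5, -4.40 for VPE2, -4.26 for MYB172, -3.74 for LAR1 and -3.64 for GDH1. KTI-2, KTI-3, AT133 and AMS1 were called higher in the cotyledon vascular bundle and lower in that of the axis. MYB172 and LAR1 were called higher in the axis alone, and all 6 cotyledon arrays of LAR1 lay below the background. With signals raised to the background, the difference was 4.70 for CHR5, 4.59 for AT133, 5.37 for AMS1, -4.35 for GY5, -3.53 for VPE2, -4.14 for MYB172, -2.76 for GDH1 and -1.70 for LAR1. LAR1 lost its call without axis vascular bundle replicate 2 (-1.91, adjusted p = 0.216) and without any 1 of 7 other arrays, and VPE2 without axis parenchyma replicate 2 (-3.38, adjusted p = 0.092) and without the 6 arrays with bright controls (-4.09, adjusted p = 0.0557). LAR1 also lost it on the arrays compared alone (adjusted p = 0.189), with pseudocount 64 (-2.45, adjusted p = 0.0612) and with quantile normalization (-3.54, adjusted p = 0.0577), and NIR with array weights (adjusted p = 0.117). The groups hold 2 arrays each, so no array was tested as an outlier.

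Chance was tested by regrouping. For cotyledon against axis, 1 of 100 splits of the 11 compartments, the real one, gave as many calls (426, and at most 66 in the others). The real split also gave the most for seed coat against axis (1 of 100, with 4512 and at most 2108) and for seed coat against cotyledon (1 of 100, with 3192 and at most 499). The 100 were drawn from 462, 462 and 126 possible splits. Compartments are not interchangeable, since the 2 parenchyma (r = 0.955) and 2 epidermis compartments (r = 0.924) of the cotyledon are closely alike. Splits that part such pairs are no fair measure of chance, so chance is not excluded at a stated level. For the cotyledon epidermis against parenchyma, fitted on its 8 arrays alone, 1 of 35 splits gave as many (2556, and at most 41). Only 3 of the 35 keep the 2 replicates of each compartment together, and those that part them gave 0 calls, so the splits of whole compartments are too few for a share under 0.05.

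The cotyledon and the axis differed in 426 probe sets, and their arrays also differed in the level of the hybridization controls (mean log2 12.35 in the cotyledon and 13.58 in the axis). Within regions, the slope of the called probe sets on that level accounts for a median of 6.43% of their differences (0.795% to 10.9% with 1 compartment left out), which argues against the control level as the main cause. With the level as a covariate 425 of 426 keep their direction, the median size goes from 1.80 to 1.71 and the median SE from 0.37 to 0.60. The differences of PARP3 (-4.31 to -2.07) and PM32 (-4.03 to -2.59) shrank by more than the median. The control level and a difference between the organs both stay open.

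Seed maturation transcripts were higher in the aleurone than in the seed coat parenchyma (list mean -0.35 against -2.59, relative to the mean over compartments) and below all 6 axis compartments (0.30 to 2.73). The list was called with the preset correlation and not with an estimated one, and some of its genes were lower or not called. As the sole source of the maturation genes called higher in the aleurone, carried-over cotyledon cells would have to make up a certain share. Their other abundant transcripts would then stand near the level that share gives. These transcripts stood at a median of 4.48% of it at most (upper end of the widest interval 17.2%). This argues against cotyledon cells as the sole source. The share needed was itself 144%, 115% and 128% for the abaxial epidermis, abaxial parenchyma and adaxial parenchyma. Carry-over as a partial source was not tested. For the axis epidermis, parenchyma, vascular bundle and shoot meristem the upper ends were 5.45%, 5.93%, 15.8% and 41.9%, which argues against each of these as the sole source. For the plumule the median was 26.8%, with an interval of 7.66% to 61.4%, and for the root meristem the interval was 2.37% to 55.8%. Cells of the plumule or root meristem and expression by the aleurone itself therefore cannot be told apart here. Both remain candidate explanations.

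In the whole seed, 607 probe sets lay above all 32 microdissected arrays and 724 below them. Chance gives 50.7 if the whole seed arrays are taken as unrelated, which replicates are not. Both arrays of a compartment lay above all other microdissected arrays for 185 (axis vascular bundle) to 1494 probe sets (hourglass layer). That chance level is therefore no fair measure. Under quantile normalization the whole seed counts were 550 and 820, and under 75th percentile scaling 406 and 1028. The counts remained under both scalings, but without a fair chance level they cannot decide whether the authors' scaling contributes. Both whole seed arrays, and no others, came from ground seed with another reagent, and their GAPDH ratios of 3' to middle signal were 15.7 and 23.2 against 64.2 to 763 in the microdissected arrays. Their actin ratios of 3' to 5' signal (108.7 and 55.9) lay within the range of the microdissected arrays (34.9 to 1211.6). Their hybridization controls were the lowest, at 0.347 and 0.291 times the median, with 0.565 the next. RNA from a different preparation and tissue missing from the 16 compartments cannot be told apart here, because the preparation follows the group.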

How the results depend on the processing

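The fits with the hybridization controls as a covariate and without the 6 arrays with bright controls were chosen after the arrays had been examined. No named gene reversed its direction in any setting, and the cause of the moved counts was not tested except where stated.

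For cotyledon against axis, 426 calls became 1047 with the compartment as a random block, and 1030 when the replicate number was added to that model. The replicate number was not added to the fit on compartment means. The calls became 3259 with compartments fixed and the replicate spread as error. They became 226 without the axis plumule, 267 without the axis vascular bundle, 228 without the cotyledon abaxial epidermis, 146 without the cotyledon abaxial parenchyma and 153 without the cotyledon adaxial parenchyma. They became 122 without the 6 arrays, which removes the axis epidermis and plumule, and 19 with the covariate. For seed coat against axis, 4512 became 7231 with compartments fixed and 2176 with the covariate, and for seed coat against cotyledon 3192 became 6542 with compartments fixed. Fixing the compartments takes arrays as the units, which by construction gives a smaller error.

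On the arrays compared alone, the counts were 733 for axis epidermis, 790 for axis vascular bundle, 572 for abaxial against adaxial epidermis and 964 for plumule against shoot meristem. These fits have fewer arrays to estimate the spread. With array weights the counts were 1020 for axis epidermis, 1294 for axis vascular bundle, 627 for abaxial against adaxial parenchyma and 532 for the epidermis interaction. With an estimated correlation 0 lists were called in place of 71.

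Leaving out 1 array leaves a lone array in its group, assumed to vary like the other groups. For enriched probe sets it also loosens the rule, as described. The counts then ranged over 1211 to 2427 for axis epidermis, 1238 to 2527 for axis vascular bundle, 1908 to 3192 for cotyledon vascular bundle, 536 to 1111 for abaxial against adaxial epidermis and 144 to 317 for abaxial against adaxial parenchyma. They ranged over 1205 to 2278 for root against shoot meristem, 789 to 1627 for plumule, 3424 to 5485 for aleurone, 2788 to 4572 for hilum and 2340 to 5693 for whole seed. For the interactions they were 586 to 1332 (epidermis) and 502 to 1273 (vascular bundle). They stayed within 1.5 times for cotyledon against axis (306 to 559), seed coat against axis (4298 to 4666) and against cotyledon (3028 to 3312), cotyledon epidermis (2866 to 3552), hourglass (3670 to 5726), palisade (3143 to 4801), the F test (16724 to 18335) and enriched probe sets (7366 to 8017).

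Genes under the background in both groups give no fold.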

Other observations

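The counts of enriched list members, the lists shown and the F test on probe sets for other organisms were chosen after the main results were seen.

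Of 5527 genes tested, 1842 were enriched in a compartment: 302 in the axis, 362 in the cotyledon and 1178 in the seed coat. Sieve element occlusion proteins had 6 of 7 genes enriched, all of them in the seed coat parenchyma. Of the 34 phenylpropanoid and flavonoid genes 26 were enriched, 13 of them in the palisade. Nitrogen genes had 7 of 15 enriched, all in the seed coat, and seed maturation proteins 11 of 29, with 6 in the shoot meristem. Among transcription factors, 14 of the 16 enriched MYB genes and 12 of the 17 enriched bZIP genes were enriched in the seed coat. Glutathione transferases had 7 of their 11 enriched genes in the cotyledon and aquaporins 5 of 10.

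The F test among the 16 compartments called 63 of 23350 probe sets for Phytophthora sojae and Heterodera glycines (0.270%), and 141 of the 4090 among them that pass the signal filter used for soybean (3.45%), against 62.0% of the soybean probe sets tested.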
